A study of Mus musculus with 24 samples.

How the data were processed

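P19 cells, a mouse embryonal carcinoma line that can differentiate when given retinoic acid, were grown in monolayer on gelatine-coated plates and profiled on 24 Affymetrix Mouse Gene 1.0 ST arrays. EtOH (ethanol) was the control, with 4 arrays that carry no time label. All-trans retinoic acid (ATRA, 1 µM), the RARα agonist BMS753 (1 µM), the RARβ agonist BMS641 (0.1 µM) and the RARγ agonist BMS961 (0.1 µM) each had 1 array at 2, 6, 24, 48 and 72 h. RAR stands for retinoic acid receptor. The doses differ between agents, so differences between the 1 µM and the 0.1 µM agents are differences between agent and dose together. The labels do not say whether the EtOH arrays or the arrays of an agent come from separate cultures, so each p-value measures the spread between these arrays, which is possibly technical in part. F9 cells, which the design text also names, were not analysed here.

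The deposited values are log2 intensities per probe set, made by the authors with Affymetrix Expression Console 1.1 and normalized between arrays. The method of background correction, summarization and normalization is not given in the sources used here. That the values are log2 was judged from their range, 2.859 to 14.3. The array medians lay between 6.502 and 6.677. The table held 35556 probe sets, of which 21789 had 1 gene symbol, 1621 had several and 12146 were not named here. Symbols came from the table of probe genes, and 21698 of these probe sets matched a gene identifier of the reference table, which changed 0 symbols. For the 999 genes with over 1 probe set, the probe set with the highest mean over all arrays was kept, which left 19938 genes. No gene was left out for low signal. The number of arrays limits the precision of every value.

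Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend=TRUE) in 1 fit of all 24 arrays. The fit had a mean for EtOH and for each agent in an early phase (2 and 6 h) and a late phase (24, 48 and 72 h), with sum-to-zero terms for time within a phase that the 4 agents shared. Arrays of a phase thus served as the repeats of an agent, n = 3 late and n = 2 early against n = 4 EtOH, and the residual held the spread of the EtOH arrays together with any agent-specific course within a phase. The residual had 12 degrees of freedom and the prior 3.10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. There were 14 comparisons: each agent late and early against EtOH, and each of the 6 pairs of agents late. Values are log2 changes with the standard error (SE) of the fit, and intervals are 95% intervals of the moderated fit. Single times were described with a fit of a mean for every agent and time, at an adjusted p under 0.05 and a change of at least 2-fold, where each lone array is assumed to vary as the EtOH arrays do.

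There were 15 gene lists with 403 genes, of which 380 had a value: retinoid pathway and known retinoid-responsive genes, Hox paralogue groups 1 to 5, Hox paralogue groups 6 to 13, pluripotency, neural progenitor, neuron, endoderm (primitive, parietal and visceral), mesoderm and cardiac, neural crest, glia, fibroblast and smooth muscle, trophoblast, cell cycle, p53 with apoptosis and stress, and cholesterol synthesis. No gene was in more than 1 list. Lists were tested against all other genes with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists and comparisons of the same kind (against EtOH, or between agents), and again with an estimated correlation. List means per array are log2 values minus the mean of the EtOH arrays. Agreement between agents was described by the correlation of late log2 changes across genes, beside 20 simulated sets of unchanged groups and beside EtOH arrays divided 2 and 2 between the agents, since the agents share their EtOH arrays.

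The groups, lists, tests of comparisons and lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls late against EtOH among called genes whose 3 late arrays all lay beyond the range of the EtOH arrays, the 5 largest each way early, the 6 largest each way between agents among called genes whose time-matched differences shared a sign, and any list member. Symbols of predicted or unnamed transcripts and of small RNAs were passed over.

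Alternatives were leaving out the 33.3% of genes with the lowest means (13292 genes left), another quantile normalization, the mean of a gene's probe sets, robust variance moderation, an added 2-fold threshold, no time term, the spread of the EtOH arrays alone, only the groups compared, and leaving out each EtOH array or each time in turn. Against EtOH, the fit of only the groups compared keeps the time terms, which fit the arrays of the agent fully. Its spread there comes from the EtOH arrays alone, so it is no separate check beside that alternative. Between agents it has fewer residual degrees of freedom than the fit of all arrays. A fit on the EtOH, BMS641 and BMS961 arrays alone was added after seeing the data. The fit of all arrays was tested on simulated data with 200 changed genes, where 76% of genes changed by a log2 of 0.50 and 98% of those changed by 1 were recovered late against EtOH, and 7 unchanged genes were called. In the simulated comparison of ATRA with BMS753 these were 72%, 90% and 9 genes. Of 20 random lists, camera called 0 in each simulated comparison. The simulated noise was independent between genes and arrays, with no agent-specific course within a phase. These shares therefore do not show what the fit recovers in the real arrays, and the random lists do not bear on lists of correlated genes.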

Results

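Gene expression was measured in P19 cells under 4 retinoids and EtOH, with 4 EtOH arrays and 1 array for each of 20 combinations of agent and time. Pairs of EtOH arrays differed by a standard deviation of 0.0941 to 0.143 log2 units across genes. The first principal component held 64.8% of the variance. The design text sets a time course of retinoic acid-induced differentiation beside agonists of single receptors, so each agent was compared with EtOH and with the other agents. No array had a replicate at its own agent and time.

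After 24 to 72 h of ATRA, P19 cells carried more of the transcripts of many Hox and retinoid genes and less of those of many pluripotency genes. Meis2, a homeobox gene of the TALE class, was 46.0-fold higher than in EtOH (log2 5.52 ± 0.29 SE, adjusted p = 3.51e-08, n = 3 and 4). Its relative Meis1 rose by 5.28 ± 0.51, Hoxa5 by 4.97 ± 0.28 and Hoxc5 by 4.55 ± 0.68. Hoxb2 rose by 4.45 ± 0.30, and Rarb, which encodes RARβ, by 4.69 ± 0.13 on the log2 scale. Pax6, a transcription factor of neural progenitors, rose by 4.01 ± 0.36, Tshz1 by 4.38 ± 0.48, Plxna2, a semaphorin receptor, by 4.17 ± 0.53 and Rasgrp3 by 4.71 ± 0.30. Tdgf1, a Nodal co-receptor of pluripotent cells, fell by 4.87 ± 0.82 and Utf1 fell by 4.16 ± 0.67. Pou5f1, which encodes Oct4, fell by 4.07 ± 0.81 and Otx2 fell by 3.41 ± 0.51. The other large falls were in Efhd1 (−3.82 ± 0.40), Il20ra (−3.60 ± 0.34), Calcr, the calcitonin receptor (−3.44 ± 0.47), Pim2 (−3.33 ± 0.65), Cyp2b23 (−3.25 ± 0.59) and Enpp3 (−3.13 ± 0.53). The adjusted p of these genes ranged up to 0.00119. Of 19938 genes tested, limma called 7362 with ATRA, 3574 higher and 3788 lower, and 939 of them changed at least 2-fold (541 higher and 398 lower).

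Of 25 measured genes of the retinoid list, 15 rose, 3 fell and 7 were not called with ATRA late, as many as adjusted over the list alone. Crabp2, a retinoic acid-binding protein, rose by 3.83 ± 0.58, and the retinoic acid hydroxylases Cyp26a1 by 3.19 ± 0.52 and Cyp26b1 by 3.16 ± 0.28. Stra6, a retinol transporter, rose by 3.12 ± 0.37 and Dhrs3, a retinal reductase, by 2.90 ± 0.15, while Rxrg fell by 2.78 ± 0.48 and Rarg fell by 1.20 ± 0.26. The list as a whole was higher (camera adjusted p = 1.39e-04), with an adjusted p = 0.143 with an estimated correlation. Of 14 genes of Hox paralogue groups 1 to 5, 13 rose and 0 fell, as many as adjusted over the list alone, with a mean log2 change of 2.80 (camera adjusted p = 7.36e-12, adjusted p = 0.266 with an estimated correlation). Of 23 genes of groups 6 to 13, 13 rose and 0 fell (14 and 0 adjusted over the list alone), among them Hoxc6 (3.04 ± 0.59), Hoxb9 (2.48 ± 0.18) and Hoxa6 (2.20 ± 0.32), with a camera adjusted p = 4.31e-04 (adjusted p = 0.670 with an estimated correlation).

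Of 34 pluripotency genes, 17 fell, 5 rose and 12 were not called with ATRA (19 and 5 adjusted over the list alone). Besides Pou5f1, Tdgf1, Utf1 and Otx2, the DNA methyltransferase gene Dnmt3b fell by 3.04 ± 0.39 and Nanog fell by 2.15 ± 0.51, whereas Tbx3 rose by 1.56 ± 0.24, Lefty2 by 1.02 ± 0.36, Nr5a2 by 0.36 ± 0.11, Klf5 by 0.32 ± 0.12 and Klf4 by 0.26 ± 0.09. The list mean was −1.07 (camera adjusted p = 0.00285, adjusted p = 0.930 with an estimated correlation). The calls of Lefty2, Klf4 and Klf5 were each lost without single EtOH arrays, that of Lefty2 without the 24 h arrays, those of Klf4, Klf5 and Nr5a2 without the 48 h or the 72 h arrays, and that of Nanog without the 48 h arrays.

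Neural lists were higher with ATRA. Of 40 neural progenitor genes, 17 rose and 4 fell (18 and 4 adjusted over the list alone), with Gbx2 at 2.91 ± 0.31, Irx3 at 2.08 ± 0.42 and Zic5 at −1.68 ± 0.34, where its dimmer probe set stood at −0.36 (camera adjusted p = 0.00193, adjusted p = 0.645 with an estimated correlation). Of 46 neuron genes, 17 rose and 4 fell (19 and 4 adjusted over the list alone). They included Lhx1 (2.91 ± 0.40), Dcx, a microtubule-binding protein of young neurons (2.71 ± 0.50), and Gap43, a growth cone protein (2.23 ± 0.24), with a camera adjusted p = 0.0189 for the list (adjusted p = 0.983 with an estimated correlation). Without the 72 h arrays the camera adjusted p of the neuron list was 0.590, and with the dimmest genes left out 0.0958. Of 32 endoderm genes, 13 rose and 2 fell (14 and 2 adjusted over the list alone), including the transcription factors Foxa1 (3.30 ± 0.33) and Gata6 (3.02 ± 0.27), the plasminogen activator gene Plat (2.64 ± 0.42) and the endocytic receptor gene Lrp2 (−0.95 ± 0.26), with a camera adjusted p = 0.00429 (adjusted p = 0.645 with an estimated correlation). The call of Lrp2 was lost without the 48 h or the 72 h arrays.

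Markers of other cell types were measured in the same arrays. Of 18 fibroblast and smooth muscle genes, 8 rose and 2 fell with ATRA (10 and 2 adjusted over the list alone), with the contractile genes Tagln at 1.82 ± 0.39 and Acta2 at 1.52 ± 0.46, Dcn at 1.86 ± 0.54, the intermediate filament gene Des at −1.24 ± 0.22 and Thy1 at −0.84 ± 0.15. The camera adjusted p of this list was 0.0429 (adjusted p = 0.983 with an estimated correlation), 0.411 without the 72 h arrays and 0.0721 with the dimmest genes left out. The call of Acta2 was lost without the 72 h arrays and that of Dcn without the 48 h arrays. Of 18 neural crest genes, 7 rose and 3 fell (9 and 3 adjusted over the list alone), with Prrx1 at 2.07 ± 0.33, Ednrb at 2.17 ± 0.54, a call lost without the 48 h arrays, and Foxd3 at −2.19 ± 0.27 (camera adjusted p = 0.195, adjusted p = 0.983 with an estimated correlation). Of 28 mesoderm and cardiac genes, 6 rose and 4 fell, as many as adjusted over the list alone, with Meox1 at 2.14 ± 0.40, the cardiac actin gene Actc1 at 1.46 ± 0.35 and Eomes at −2.30 ± 0.32 (camera adjusted p = 0.689, adjusted p = 0.983 with an estimated correlation). Of 14 glia genes, 1 rose (Slc1a2, 0.53 ± 0.12) and 2 fell, among them Aldh1l1 (−1.57 ± 0.17), as many as adjusted over the list alone (camera adjusted p = 0.895, adjusted p = 0.983 with an estimated correlation). Of 12 trophoblast genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Gata3 at 2.10 ± 0.34 and Cited1 at −2.69 ± 0.41. Their mean was −0.01, their median 0.23 and the direction of the test up (camera adjusted p = 0.772, adjusted p = 0.983 with an estimated correlation).

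Of 34 cell cycle genes, 6 rose and 13 fell with ATRA (8 and 13 adjusted over the list alone), with the cyclin genes Ccnd2 at 1.37 ± 0.27 and Ccnd1 at −0.93 ± 0.17. The camera adjusted p was 0.135 (adjusted p = 0.983 with an estimated correlation) and 0.00571, with the list lower, without the 48 h arrays. Of 25 p53, apoptosis and stress genes, 5 rose and 9 fell, as many as adjusted over the list alone, with Plk2, a p53 target, at 2.98 ± 0.37 (camera adjusted p = 0.357, adjusted p = 0.983 with an estimated correlation). The falls included Trib3 (−1.71 ± 0.20) and Chac1 (−1.28 ± 0.17), targets of the transcription factor ATF4. Of 17 cholesterol synthesis genes, 6 fell and 1 rose (8 and 1 adjusted over the list alone), with Dhcr7 at −0.61 ± 0.11, Pmvk at −0.54 ± 0.13, Lss at −0.52 ± 0.14 and Sc5d at 0.30 ± 0.07. The list was lower with a camera adjusted p = 0.0106 (adjusted p = 0.983 with an estimated correlation), and the adjusted p was 0.582 without the 72 h arrays, 0.0681 after another quantile normalization and 0.0721 with the dimmest genes left out. The call of Lss was lost without the 72 h arrays and that of Sc5d without the 48 h arrays.

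**Figure D1:**
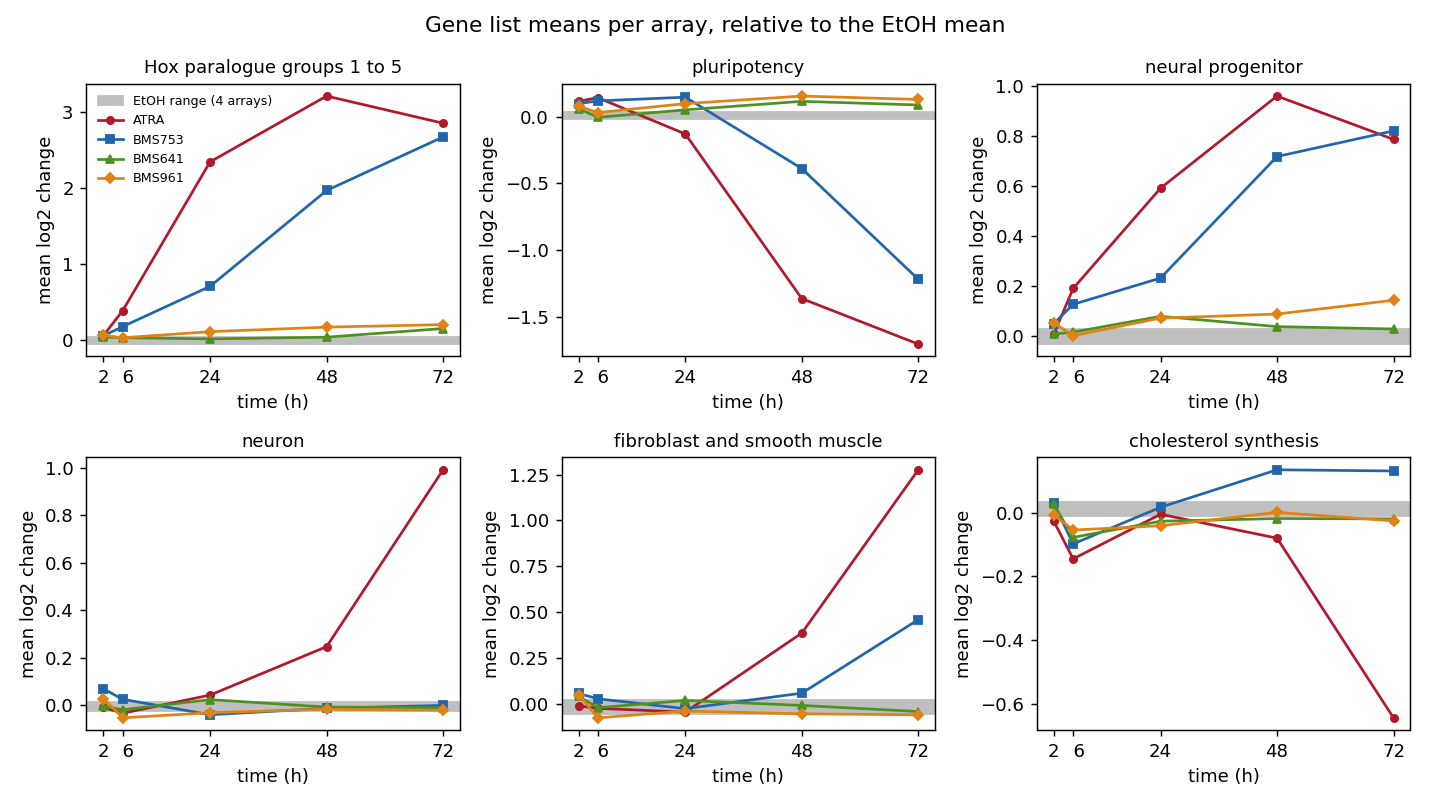
Mean log2 change of 6 gene lists in each array against time in hours, relative to the mean of the 4 EtOH arrays, with the range of the EtOH arrays in grey and 1 point per array. At 72 h the neuron list stood at 0.99 with ATRA and −0.00 with BMS753, and Hox paralogue groups 1 to 5 at 2.85 and 2.67.

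BMS753, the RARα agonist, was given at the same dose as ATRA, and its late arrays differed from EtOH in many genes that ATRA also changed. Meis2 rose by 4.83 ± 0.29 (28.5-fold, adjusted p = 4.10e-07, n = 3 and 4), Rarb by 4.19 ± 0.13, Meis1 by 3.85 ± 0.51, the casein gene Csn3 by 3.76 ± 0.40, Hoxb2 by 3.54 ± 0.30 and Hoxa2 by 3.40 ± 0.27. Tshz1 rose by 3.37 ± 0.48, Greb1l by 3.28 ± 0.43, the secreted signal Wnt1 by 3.10 ± 0.56 and Hoxa5 by 3.04 ± 0.28. Efhd1 fell by 2.92 ± 0.40, Tdgf1 fell by 2.74 ± 0.82, Calcr fell by 2.72 ± 0.47, Il20ra fell by 2.66 ± 0.34, Slc35d3 fell by 2.41 ± 0.40. Prrg4 fell by 2.19 ± 0.34, Hsd17b11 fell by 2.18 ± 0.36 and Foxi3 fell by 2.08 ± 0.32. Pcolce2 (−1.99 ± 0.34) and Gstk1 (−1.98 ± 0.27) completed the 10 largest falls. The adjusted p of these genes ranged up to 0.0361, that of Tdgf1. limma called 2683 genes, 1299 higher and 1384 lower, of which 412 changed at least 2-fold (238 higher and 174 lower). The count was 5364 without the 24 h arrays, 1051 without the 48 h arrays, 1510 without the 72 h arrays and 6247 with the spread of the EtOH arrays alone. The call of Tdgf1 was lost without the 48 h or the 72 h arrays, without any single EtOH array, or without a time term.

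Of the 25 retinoid genes, 9 rose and 1 fell with BMS753 late (9 and 3 adjusted over the list alone), with Crabp2 at 2.89 ± 0.58, Cyp26a1 at 2.65 ± 0.52, Crabp1 at 2.40 ± 0.51, Stra6 at 2.13 ± 0.37 and Dhrs3 at 1.68 ± 0.15 (camera adjusted p = 5.82e-05, adjusted p = 0.143 with an estimated correlation). Of the 14 genes of Hox groups 1 to 5, 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a mean of 1.78 (camera adjusted p = 1.69e-13, adjusted p = 0.238 with an estimated correlation). Of the 23 genes of groups 6 to 13, 2 rose, Hoxb9 (1.07 ± 0.18) and Hoxa7 (0.65 ± 0.15), as many as adjusted over the list alone (camera adjusted p = 0.295, adjusted p = 0.983 with an estimated correlation). Of 34 pluripotency genes, 8 fell and 0 rose (10 and 2 adjusted over the list alone), with Fgf4 at −1.65 ± 0.34, Otx2 at −1.62 ± 0.51 and Dnmt3b at −1.54 ± 0.39 (camera adjusted p = 0.0285, adjusted p = 0.983 with an estimated correlation). The camera adjusted p was 0.729 without the 72 h arrays. Pou5f1, at −1.86 ± 0.81, was not called (adjusted p = 0.152). Crabp1, Fgf4, Otx2 and Dnmt3b lost their calls without the 48 h or the 72 h arrays, Crabp2 and Hoxa7 without the 48 h arrays, and Otx2 also without any single EtOH array.

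Of 40 neural progenitor genes, 12 rose and 3 fell with BMS753 (14 and 3 adjusted over the list alone), with Pax3 at 2.56 ± 0.48, Pax6 at 2.25 ± 0.36, the Notch ligand gene Dll1 at 1.60 ± 0.36 and Fabp7 at 1.27 ± 0.32 (camera adjusted p = 0.00163, adjusted p = 0.645 with an estimated correlation). Of 46 neuron genes, 3 rose (Lhx1, 1.83 ± 0.40, Gap43, 1.73 ± 0.24, and Dpysl3, 0.66 ± 0.16) and 4 fell (4 and 4 adjusted over the list alone), with a camera adjusted p = 0.895 (adjusted p = 0.983 with an estimated correlation). Of 32 endoderm genes, 3 rose, Foxa1 (1.87 ± 0.33), Gata6 (1.82 ± 0.27) and Sox17 (0.47 ± 0.14), as many as adjusted over the list alone (camera adjusted p = 0.0653, adjusted p = 0.983 with an estimated correlation). The camera adjusted p was 0.0178 without the 24 h arrays and 0.0438 after another quantile normalization. Of 18 neural crest genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone), with Tfap2b at 1.92 ± 0.56 and Msx1 at 1.90 ± 0.48 (camera adjusted p = 0.178, adjusted p = 0.983 with an estimated correlation), and the camera adjusted p was 0.0439 without the 48 h arrays. Of 18 fibroblast and smooth muscle genes, 2 fell and 0 rose, as many as adjusted over the list alone (camera adjusted p = 0.603, adjusted p = 0.983 with an estimated correlation). The remaining lists had camera adjusted p from 0.123 (cholesterol synthesis, 0.0197 without the 72 h arrays) to 0.964 (trophoblast). The calls of Dll1, Lhx1, Sox17, Msx1 and Tfap2b were lost without the 48 h or the 72 h arrays, that of Dpysl3 without the 48 h arrays, that of Fabp7 without the 72 h arrays, and those of Sox17 and Tfap2b also without any single EtOH array.

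ATRA and BMS753, both at 1 µM, were compared directly over 24, 48 and 72 h. Cyp26b1 was 2.50 ± 0.30 higher with ATRA on the log2 scale (adjusted p = 5.77e-04, n = 3 and 3), Mme, which encodes neprilysin, 2.11 ± 0.22, Ifi203 2.82 ± 0.75, the alcohol dehydrogenase gene Adh1 2.14 ± 0.60, Hoxc6 2.11 ± 0.63 and Zfp804a 2.10 ± 0.58. Lower with ATRA were Mogat2 (−2.42 ± 0.42), Cyp2b23 (−2.22 ± 0.63), Pla2g7 (−2.16 ± 0.30), Fgf15 (−2.05 ± 0.41), Nanog (−2.05 ± 0.55) and Slc7a11, the cystine transporter (−1.99 ± 0.41). limma called 2067 genes, 885 higher and 1182 lower with ATRA, and 143 of them differed at least 2-fold. The count was 4735 without the 24 h arrays, 317 without the 48 h arrays, 1022 without the 72 h arrays, 7024 with the spread of the EtOH arrays alone and 0 in a fit of only these arrays. In that last fit each of the 12 genes just named lost its call. It has fewer residual degrees of freedom than the fit of all arrays, so calls can be lost there through low power alone. Of these 12, only Cyp26b1, Mme and Pla2g7 held without the 48 h arrays, and the calls of Hoxc6 and Cyp2b23 were lost without any single EtOH array. Without the 72 h arrays Ifi203, Adh1, Hoxc6, Zfp804a and Slc7a11 lost theirs.

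Genes of several lists differed between ATRA and BMS753 late. Of 14 genes of Hox groups 1 to 5, 8 were higher with ATRA and 0 lower (10 and 0 adjusted over the list alone), with Hoxb5 at 2.04 ± 0.33 and Hoxa5 at 1.93 ± 0.30 (camera adjusted p = 7.08e-06, adjusted p = 0.442 with an estimated correlation). For Hoxa2 the difference was −0.12, with an interval of −0.72 to 0.49. Of 23 genes of groups 6 to 13, 7 were higher and 0 lower (11 and 0 adjusted over the list alone), with Hoxb9 at 1.42 ± 0.20 (camera adjusted p = 7.08e-06, adjusted p = 0.442 with an estimated correlation). Of 46 neuron genes, 5 were higher and 0 lower (15 and 0 adjusted over the list alone), with Dcx at 2.02 ± 0.53, Ebf1 at 1.51 ± 0.35, the neurofilament gene Nefm at 1.40 ± 0.36 and Dpysl3 at 1.02 ± 0.17 (camera adjusted p = 1.48e-05, adjusted p = 0.529 with an estimated correlation). Of 17 cholesterol synthesis genes, 6 were lower and 0 higher (16 and 0 adjusted over the list alone), with Lss at −0.62 ± 0.15, Pmvk at −0.59 ± 0.14 and Dhcr7 at −0.58 ± 0.12 (camera adjusted p = 1.34e-07, adjusted p = 0.442 with an estimated correlation). Of these genes, Hoxb5, Dcx, Ebf1, Nefm, Lss, Pmvk and Dhcr7 lost their calls without the 48 h arrays, and Dcx, Ebf1 and Nefm without the 72 h arrays.

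Of 34 pluripotency genes, 5 were lower and 2 higher with ATRA than with BMS753 (8 and 2 adjusted over the list alone), with Otx2 at −1.80 ± 0.54, Dnmt3b at −1.50 ± 0.42 and Sall4 at −1.18 ± 0.30 (camera adjusted p = 0.0165, adjusted p = 0.690 with an estimated correlation), and the camera adjusted p was 0.0927 without the 48 h arrays. Pou5f1 differed by −2.21, with an interval of −4.05 to −0.36 and an adjusted p = 0.107. Of 32 endoderm genes, 3 were higher and 1 lower (7 and 1 adjusted over the list alone), with Foxa1 at 1.43 ± 0.35, Gata6 at 1.20 ± 0.28 and Lrp2 at −1.23 ± 0.28 (camera adjusted p = 0.00611, adjusted p = 0.442 with an estimated correlation). Of 25 retinoid genes, 4 were higher and 0 lower (5 and 0 adjusted over the list alone), with Dhrs3 at 1.22 ± 0.16 and Rarb at 0.50 ± 0.14 (camera adjusted p = 0.0301, adjusted p = 0.442 with an estimated correlation). The camera adjusted p of the retinoid list was 0.374 without the 24 h arrays. Meis2 differed by 0.69 (interval 0.03 to 1.35, adjusted p = 0.153) and Crabp1 by −0.10 (interval −1.26 to 1.07). Of 40 neural progenitor genes, 4 were higher and 2 lower (6 and 2 adjusted over the list alone), with Fabp7 at −1.15 ± 0.34 and Zic1 at −0.75 ± 0.15 (camera adjusted p = 0.110, adjusted p = 0.721 with an estimated correlation). The neural progenitor list had a camera adjusted p of 0.0116 without the 72 h arrays. Otx2, Dnmt3b, Sall4, Foxa1, Gata6, Lrp2, Rarb and Fabp7 lost their calls without the 48 h arrays, Lrp2, Rarb and Fabp7 also without the 72 h arrays, Rarb without the 24 h arrays, Rarb without EtOH replicate 4, and Otx2 and Fabp7 without any single EtOH array.

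Of 34 cell cycle genes, 4 were lower and 0 higher with ATRA than with BMS753 (7 and 0 adjusted over the list alone), with a camera adjusted p = 0.00482 (adjusted p = 0.604 with an estimated correlation). That adjusted p was 0.770 without the 72 h arrays, 0.149 after another quantile normalization and 0.0621 with the dimmest genes left out. Of 18 fibroblast and smooth muscle genes, 0 were called by limma either way, 0 adjusted over the list alone, although the list was higher with ATRA (mean 0.37, camera adjusted p = 0.0217, adjusted p = 0.712 with an estimated correlation). That adjusted p was 0.219 without the 72 h arrays. The remaining lists had camera adjusted p from 0.159 (p53, apoptosis and stress, 0.0365 without the 24 h arrays) to 0.897 (glia).

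The changes with ATRA and BMS753 correlated across genes (Pearson's r = 0.834, and 0.814 with separate EtOH arrays), where unchanged groups that share EtOH arrays gave a simulated r of 0.427. Genes are not independent replicates. Both agents raised 1034 genes, where independent lists would share 233, and lowered 1160, where they would share 263. With separate EtOH arrays the lists were shorter, and the mean shared counts were 349 and 390, or 6.99 and 6.27 times those of independent lists of these lengths. Opposite calls were made for 3 genes, Hs3st5, Klf4 and Lta, named here after their values were seen. Of these, Hs3st5 was also low in the late BMS641 and BMS961 arrays (−0.38 to −0.16).

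**Figure D2:**
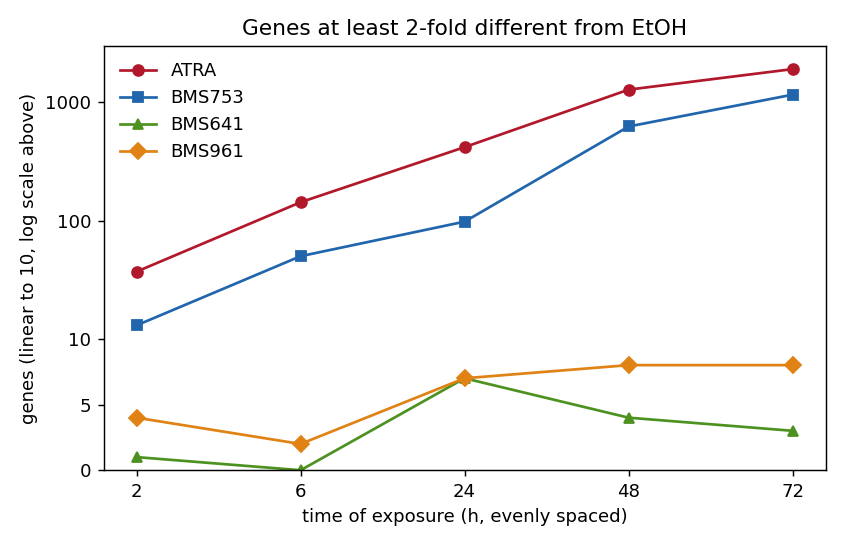
Number of genes called with at least a 2-fold difference from EtOH at each time in hours, 1 array per agent and time, each lone array assumed to vary as the 4 EtOH arrays do. Counts from single arrays describe these arrays only and cannot separate an agent from variation between cultures.

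Single arrays give the course of these changes. Across genes, the difference from the EtOH mean had an SD of 0.140, 0.222, 0.348, 0.577 and 0.703 with ATRA at 2, 6, 24, 48 and 72 h. With BMS753 that SD was 0.118, 0.159, 0.195, 0.392 and 0.533. Rarb stood 3.12 above EtOH after 2 h of ATRA and 4.73 above it at 72 h. Cyp26a1 reached 4.71 at 24 h of ATRA and stood at 0.93 at 72 h, where BMS753 gave 2.00. Pou5f1 stood at −0.49, −4.28 and −7.45 at 24, 48 and 72 h of ATRA, and at −0.11, −1.47 and −4.02 with BMS753. Nanog stood at 1.25 after 24 h of BMS753 and at −1.63 after 72 h. Dcx reached 4.87 at 72 h of ATRA against 1.34 with BMS753. The pluripotency list mean at 72 h was −1.71 with ATRA and −1.22 with BMS753, that of the fibroblast and smooth muscle list 1.28 and 0.46, and that of the cholesterol synthesis list −0.64 and 0.13. These are single arrays, so no difference between agents at a single time was tested.

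**Figure D3:**
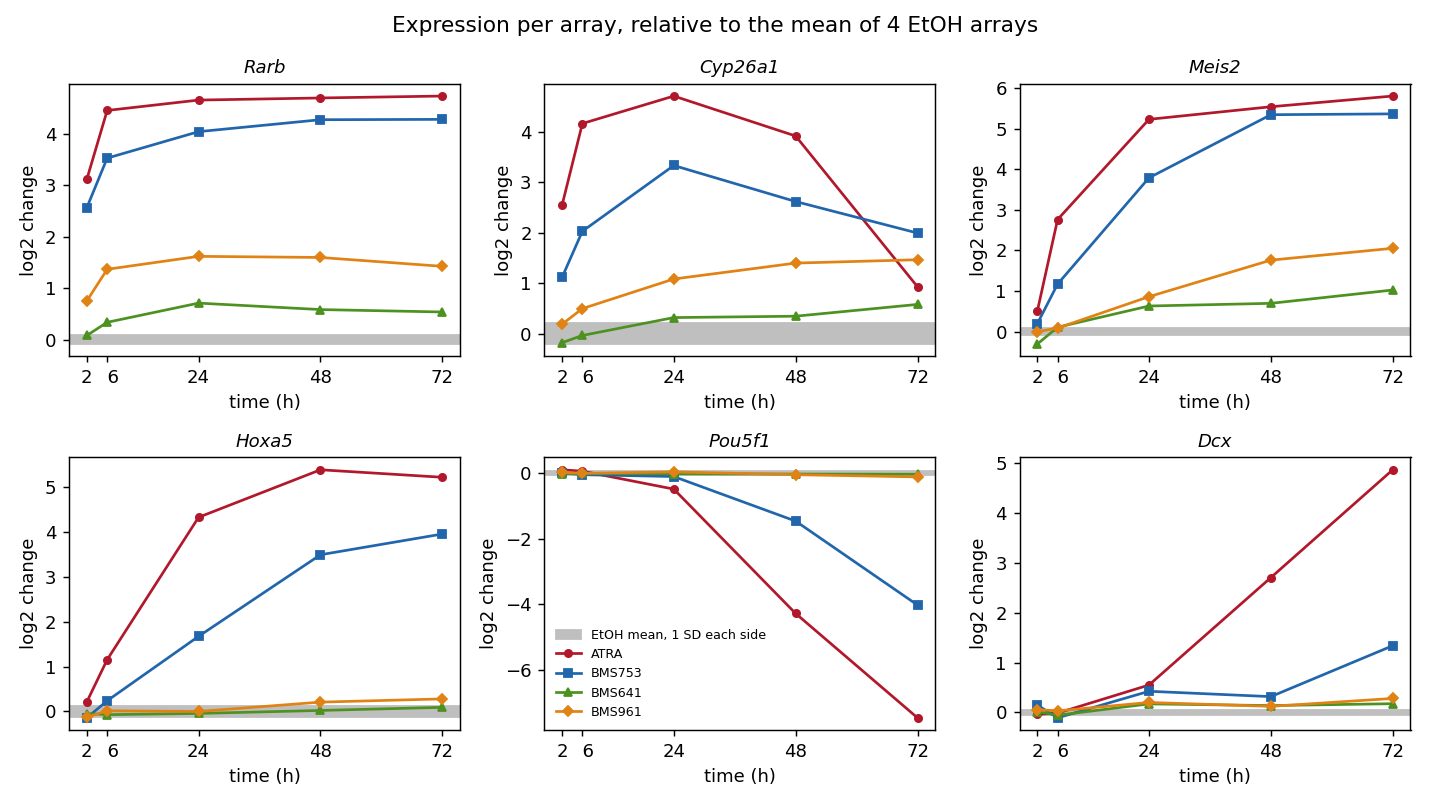
Log2 change of 6 genes in each array against time in hours, relative to the mean of the 4 EtOH arrays, with 1 SD of the EtOH arrays on each side in grey. Pou5f1 stood at −7.45 at 72 h of ATRA and −4.02 with BMS753, and Cyp26a1 at 4.71 at 24 h of ATRA and 0.93 at 72 h.

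In the early phase, at 2 and 6 h, genes of the retinoid list were among the largest rises. With ATRA, Rarb rose by 3.78 ± 0.15 (adjusted p = 1.77e-09, n = 2 and 4), Cyp26a1 by 3.36 ± 0.59, Csn3 by 2.52 ± 0.45, Adgra2 by 2.30 ± 0.33 and Gbx2 by 2.11 ± 0.35. List members that rose included Dhrs3 (2.01 ± 0.17), Hoxb13 (1.91 ± 0.18), Gata6 (1.84 ± 0.30), Foxa1 (1.80 ± 0.37), Meis2 (1.63 ± 0.33), Nrip1 (0.98 ± 0.09) and Rara (0.84 ± 0.09). The 5 largest falls were smaller, in Ptger4 (−0.68 ± 0.14), Nkx2-9 (−0.53 ± 0.08), Egr2 (−0.47 ± 0.09), Hes1, a Notch target (−0.47 ± 0.10), and St8sia4 (−0.44 ± 0.07). limma called 171 genes, 164 higher and 7 lower, and 44 of them, all higher, changed at least 2-fold. The count was 18 without the 6 h arrays, 109 without EtOH replicate 2, 112 without a time term and 1402 with the spread of the EtOH arrays alone. Of the genes named here, Rarb, Dhrs3, Hoxb13 and Nrip1 kept their calls without the 6 h arrays, Ptger4, Egr2 and Hes1 lost theirs without the 2 h arrays, and Ptger4, Egr2, Hes1, Foxa1 and Meis2 lost theirs without 1 or more of the EtOH arrays.

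With BMS753 early, Rarb rose by 3.04 ± 0.15 (adjusted p = 4.31e-08, n = 2 and 4), the kinase gene Plk3 by 1.64 ± 0.19, Dhrs3 by 1.37 ± 0.17, the phosphatase gene Dusp9 by 1.35 ± 0.20, Kcnip3 by 1.20 ± 0.24, Hoxb13 by 0.97 ± 0.18, Nrip1 by 0.67 ± 0.09 and Rara by 0.44 ± 0.09. Gal3st2c fell by 0.39 ± 0.07 and was the only gene called lower. Cyp26a1 stood at 1.57 ± 0.59 and was not called (adjusted p = 0.350). limma called 61 genes, 60 higher and 1 lower, and 7 of them changed at least 2-fold. The count was 22 without the 2 h arrays, 2 without the 6 h arrays, 26, 29, 31 and 25 without EtOH replicates 1, 2, 3 and 4, 26 without a time term, 29 after another quantile normalization and 908 with the spread of the EtOH arrays alone. Of the genes named here, only Rarb kept its call without the 6 h arrays, and only Rarb, Dhrs3 and Dusp9 without the 2 h arrays. Kcnip3, Gal3st2c, Hoxb13 and Rara lost theirs without 1 or more of the EtOH arrays. The difference between ATRA and BMS753 in the early phase was not tested.

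BMS961 and BMS641, the RARγ and RARβ agonists, were both given at 0.1 µM, a lower dose than that of ATRA and BMS753. With BMS961 late, Rarb rose by 1.55 ± 0.13 (2.92-fold, adjusted p = 1.10e-04, n = 3 and 4) and was the only gene called by limma, while 769 genes had an unadjusted p under 0.05. Gfra1, which encodes a receptor for GDNF, stood at 1.91 ± 0.30 (adjusted p = 0.0710), Meis2 at 1.56 ± 0.29 (adjusted p = 0.196) and Dhrs3 at 0.90 ± 0.15 (adjusted p = 0.0995). With BMS641 late, limma called 0 genes, with 625 at an unadjusted p under 0.05, and Gfra1 stood at 1.31 ± 0.30, Meis2 at 0.78 ± 0.29 and Rarb at 0.61 ± 0.13. The counts of 769 and 625 are both below the share of 0.05 of the 19938 genes tested that chance alone would give. Gfra1 was named after its values were seen. The retinoid list was higher with BMS961, with 1 of 25 genes risen and 0 fallen (2 and 0 adjusted over the list alone, camera adjusted p = 0.0101, adjusted p = 0.370 with an estimated correlation). Of 28 mesoderm and cardiac genes with BMS641, 0 were called by limma, 0 adjusted over the list alone, with a list mean of 0.06 (camera adjusted p = 0.0372, adjusted p = 0.670 with an estimated correlation). That adjusted p was 0.0553, 0.0519 and 0.0708 without the 24, 48 and 72 h arrays, and 0.0699 after another quantile normalization. The retinoid list and Hox groups 6 to 13 were not called with BMS641 (camera adjusted p = 0.336 and 0.357, adjusted p = 0.983 with an estimated correlation in both) but were higher with the dimmest genes left out (camera adjusted p = 0.0433 in both). With BMS961, Hox groups 1 to 5 had a camera adjusted p = 0.276 (adjusted p = 0.983 with an estimated correlation) and 0.0476 without the 24 h arrays.

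The counts for BMS641 and BMS961 moved with the arrays in the fit. The spread of the fit of all arrays holds the courses of ATRA and BMS753. In the fit of the EtOH, BMS641 and BMS961 arrays alone, chosen after seeing the data, limma called 634 genes with BMS961 late (321 higher and 313 lower) and 191 with BMS641 late (124 higher and 67 lower). In that fit Gfra1 rose by 1.91 ± 0.05, Greb1l by 1.58 ± 0.06, Meis2 by 1.56 ± 0.11, Rarb by 1.55 ± 0.07, Cltb by 1.38 ± 0.08, Cyp26a1 by 1.32 ± 0.09 and the Wnt acyltransferase gene Porcn by 1.05 ± 0.05 with BMS961. With BMS641, Greb1l rose by 1.33 ± 0.06, Gfra1 by 1.31 ± 0.05, Cltb by 1.02 ± 0.08, Porcn by 1.00 ± 0.05, Nr0b1 by 0.89 ± 0.04 and Actn3 by 0.88 ± 0.04. Of the 321 genes higher with BMS961, 141 were also called higher and 47 lower with ATRA late, and of the 313 lower, 198 were also lower and 30 higher with ATRA. Of the 124 genes higher with BMS641, 59 were higher and 14 lower with ATRA, and of the 67 lower, 44 were lower and 4 higher. Lists independent of those of ATRA would share 57.5 higher and 59.5 lower genes for BMS961, and 22.2 and 12.7 for BMS641. The agents share their EtOH arrays, which alone brings some calls of the same direction, and the overlap was not tested. With the spread of the EtOH arrays alone the late counts were 456 with BMS961 and 125 with BMS641, and with only the groups compared 464 and 115. Both alternatives take their spread from the EtOH arrays alone, so their near-equal counts were fixed by construction. The BMS961 count was 0 without a time term, which ended the call of Rarb, and 7 without the 24 h arrays.

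In the early phase limma called 0 genes with BMS641 and 0 with BMS961, with 468 and 582 at an unadjusted p under 0.05. Both are below the share of 0.05 of the 19938 genes tested that chance alone would give. The lowest adjusted p with BMS961 was 0.0706, for Rarb. In the fit of the EtOH, BMS641 and BMS961 arrays the early counts were 58 and 109. In it Plk3 rose by 0.72 ± 0.06, Hoxb13 by 0.63 ± 0.08, Nr0b1 by 0.61 ± 0.05 and Dhrs3 by 0.45 ± 0.05 with BMS641, and Rarb rose by 1.06 ± 0.07, Plk3 by 0.85 ± 0.06 and Dhrs3 by 0.71 ± 0.05 with BMS961. The early counts were 30 and 70 with the spread of the EtOH arrays alone and 28 and 70 with only the groups compared, which also takes its spread from the EtOH arrays alone. BMS641 had 1 call without the 6 h arrays and BMS961 had 2 without the 2 h arrays.

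BMS641 and BMS961 had the same dose, and their late arrays were compared directly. limma called 0 genes between them, with 358 at an unadjusted p under 0.05, below the share of 0.05 of the 19938 genes tested that chance alone would give. BMS641 minus BMS961, Rarb differed by −0.93, with an interval of −1.24 to −0.63 and the lowest adjusted p, 0.155. For Cyp26a1 the difference was −0.90 (interval −2.10 to 0.29), for Meis2 −0.77 (−1.44 to −0.11), for Gfra1 −0.60 (−1.27 to 0.08), for Greb1l −0.25 (−1.23 to 0.72) and for Porcn −0.05 (−0.90 to 0.80). The interval lay within 1 log2 unit of 0 for 99.0% of genes, with a median half-width of 0.167. In the fit of the EtOH, BMS641 and BMS961 arrays 30 genes were called, 8 higher and 22 lower with BMS641, among them Rarb, Cyp26a1, Meis2 and Gfra1. The count was 20 with the spread of the EtOH arrays alone and 69 with only the groups compared. The retinoid list was lower with BMS641 than with BMS961, with 0 of 25 genes called (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0127, adjusted p = 0.442 with an estimated correlation). The mesoderm and cardiac list was higher with BMS641, with 0 of 28 genes called by limma, 0 adjusted over the list alone (mean 0.05, camera adjusted p = 0.0116, adjusted p = 0.442 with an estimated correlation), and the camera adjusted p was 0.108 without the 48 h arrays. The late changes with BMS641 and BMS961 correlated across genes at r = 0.691, where simulated unchanged groups that share EtOH arrays gave 0.427. With separate EtOH arrays r was 0.380. The simulated value is no reference for it, since separate arrays remove the shared part, and unchanged groups with separate EtOH arrays were not simulated.

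ATRA and BMS753 were each also compared with the agents given at the lower dose. ATRA was above BMS641 in Meis1 by 5.04 ± 0.55, Hoxa5 by 4.95 ± 0.30, Meis2 by 4.74 ± 0.31, Rasgrp3 by 4.69 ± 0.32, Hoxc5 by 4.54 ± 0.73 and Tshz1 by 4.49 ± 0.51. It was below BMS641 in Tdgf1 (−4.92 ± 0.87), Pou5f1 (−4.04 ± 0.87), Utf1 (−4.02 ± 0.72), Nr0b1 (−3.54 ± 0.84), Efhd1 (−3.52 ± 0.43) and Il20ra (−3.49 ± 0.36). Against BMS961 the 6 largest differences each way held the same genes except Crabp2 (4.09 ± 0.63) in place of Meis2 and Pim2 (−3.40 ± 0.69) in place of Nr0b1. limma called 6348 genes against BMS641 and 6377 against BMS961, 2987 and 3052 of them higher with ATRA, with n = 3 and 3. The first count was 3664 without the 48 h arrays, the other 3526 without the 48 h and 4248 without the 72 h arrays, and in fits of only the groups compared they were 26 and 30. Lists that camera called with ATRA late against EtOH were also called against both agents, in the same direction. With an estimated correlation all these list calls were lost. Those of the neuron, fibroblast and smooth muscle and cholesterol synthesis lists were also lost without the 72 h arrays. With the dimmest genes left out, those of neuron and of fibroblast and smooth muscle against BMS641 were lost. Those of cholesterol synthesis against both agents were lost in that setting and after another quantile normalization.

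BMS753 was above BMS641 in Meis2 by 4.05 ± 0.31, Meis1 by 3.61 ± 0.55, Rarb by 3.58 ± 0.14, Tshz1 by 3.48 ± 0.51, Hoxb2 by 3.39 ± 0.32 and Hoxa2 by 3.25 ± 0.28. It was below BMS641 in Efhd1 (−2.61 ± 0.43), Calcr (−2.61 ± 0.51), Il20ra (−2.56 ± 0.36), Slc35d3 (−2.23 ± 0.42), the chemokine gene Ccl17 (−2.04 ± 0.40) and Foxi3 (−2.03 ± 0.34). Against BMS961, Meis1 (3.42 ± 0.55), Meis2 (3.27 ± 0.31), Tshz1 (3.27 ± 0.51), Crabp2 (3.16 ± 0.63), Hoxb2 (3.03 ± 0.32) and Rasgrp3 (2.99 ± 0.32) were higher with BMS753. Calcr (−2.63 ± 0.51), Efhd1 (−2.53 ± 0.43), Il20ra (−2.46 ± 0.36), Slc35d3 (−2.18 ± 0.42), Gca (−2.07 ± 0.38) and Pdzd4 (−1.99 ± 0.51) were lower. limma called 1980 genes against BMS641 and 1575 against BMS961, 1023 and 834 of them higher with BMS753. The counts were 4350 and 4247 without the 24 h arrays, 130 and 59 without the 48 h arrays, 497 and 255 without the 72 h arrays, 1011 and 641 without a time term, 5859 and 5591 with the spread of the EtOH arrays alone, and 4 and 4 in fits of only the groups compared. Hox groups 1 to 5 were higher with BMS753 in 10 of 14 genes against BMS641 and 11 against BMS961, with 0 lower in either (14 adjusted over the list alone in both, camera adjusted p = 4.73e-14 and 4.25e-14, adjusted p = 0.156 with an estimated correlation in both). Against both, camera also called the retinoid, neural progenitor, endoderm and cholesterol synthesis lists higher and the pluripotency list lower. With an estimated correlation these calls were lost, those of endoderm also without the 48 h or the 72 h arrays or the dimmest genes. Those of pluripotency were also lost without the 72 h arrays, and that of cholesterol synthesis against BMS641 without the dimmest genes.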

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

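The tests of the 39 genes outside the ATRA range (apart from their share, tested as planned), of ATRA arrays left out of their own course, of a response reduced in proportion, of the between-array normalization, of a mixed culture, of admixed fibroblasts and of the splits in the fit of the EtOH, BMS641 and BMS961 arrays were chosen after the result was seen. Of these, the test of proportion on lists replaced a first version on the neuron list at 72 h alone (−37.1 EtOH standard deviations), and the test of a mixed culture replaced one in EtOH standard deviations (10.4), because both set single arrays against a spread that is possibly technical. The bounds of the test of proportion on lists were reworded once more after its value, 0.603, was seen, when a first wording had it favour a reduction in proportion. The bounds for the 39 genes outside the ATRA range were also changed more than once after the count was seen. Earlier versions had counted them against a delay or against a reduction in proportion, beside 4 genes for BMS961 and 0 for BMS641, arrays with too few changes to serve as a reference, or had set them beside 61 genes that the ATRA 24 and 48 h arrays, left out together, put outside the range of the others, which is no fair reference because it takes away the middle of the course. A bound of 5% of calls, for these genes and for the 3 called in opposite directions, was also dropped, because 39 genes could not have reached it. The first version of the mixed culture test had the same outcome as the one below, where the value is 0.335.

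ATRA and BMS753 differed in 2067 genes late, and 1606 were called after another quantile normalization, 1427 of them shared with the 2067. The count stayed within 1.5 times, the bound chosen against the normalization as the source. That step worked on values already normalized between arrays and cannot undo the first one, so it does not settle whether the authors' normalization is a source. A reduction of the ATRA response in proportion at matched times would not put genes beyond ATRA, and 39 of 7848 genes called late with either agent lay over 0.5 log2 units outside the range of the ATRA and EtOH arrays at both 48 and 72 h of BMS753, but these are single arrays, 10 of the 39 were called between the agents, and 1 of those 10 kept its call without the 48 h arrays and 1 without the 72 h arrays. On lists the test did not decide, as Hox groups 1 to 5 lay above the neuron list by −0.14, 0.43 and 1.52 after scaling at 24, 48 and 72 h (mean 0.603, SD 0.840). Of the 2197 genes called with both agents, 3 were called in opposite directions, each losing its BMS753 call without the 48 h arrays. Over the 7848 genes, the root-mean-square distance of BMS753 from the scaled ATRA array was 0.165, 0.363 and 0.469 at these times. Between 2 EtOH arrays it was 0.108, and late BMS641 and BMS961 arrays differed from the EtOH mean by SDs of 0.0973 to 0.122 over all genes. The 48 and 72 h distances lay above both. The EtOH arrays are possibly technical repeats, and the SDs were taken over all genes in arrays with few changes. With 1 array per time, these distances do not settle whether 1 scale factor holds for these genes as a set. A BMS753 response that runs through the ATRA course with a delay is a candidate explanation that stays open, since the share outside the range (0.497%) met the bound of under 1% set beforehand for a delay but would be as low for any weaker response, and for the 39 genes too, since the BMS753 48 and 72 h arrays lay closest to the ATRA course at an interpolated 30.7 and 41.8 h, where no ATRA array was taken, and an effect of the agent itself was not tested apart from these. From the interpolated ATRA course the BMS753 72 h array lay at 3.30 times the distance between EtOH arrays. This met the bound of over 3 times set beforehand against a delay. That bound, judged wrong after the value was seen, set 1 array against EtOH arrays that are possibly technical repeats. The ATRA 24 and 48 h arrays, each left out in turn, lay at 2.81 and 3.38 times the distance between EtOH arrays from the other ATRA arrays, across wider gaps in time.

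The fibroblast and smooth muscle list stood at 1.28 in the ATRA 72 h array. The ATRA 48 h (0.39) and BMS753 72 h (0.46) arrays were both at least 0.335 above the highest of the 14 EtOH, BMS641 and BMS961 arrays (0.05). They argue against a mixed culture in the ATRA 72 h array as the source of the whole pattern. Both stood lower than that array, so they cannot exclude that a mixed culture added to its value. Admixed fibroblasts cannot be told apart from a change in the P19 cells: of 7 abundant fibroblast transcripts in the ATRA 72 h array, Col1a2 (1.21), Col3a1 (1.18), Vim (0.73), Col1a1 (0.39), S100a4 (0.32) and Lum (0.29) were above the highest EtOH array and 1, Thy1 (−0.94), was not. Vim stood at 12.8 and Thy1 at 7.77 in EtOH, so the cells express both without ATRA. Differentiation of P19 cells under ATRA stays open as an untested biological explanation.

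Genes called higher early with ATRA were also higher late with BMS961. With separate EtOH arrays for calling and measuring, the lists were shorter, 49 to 61 genes, and their mean change with BMS961 was 0.218. The SD over 6 divisions of the EtOH arrays was 0.0135, but each division used the same ATRA and BMS961 arrays, so it does not measure their spread. For these shorter lists the value argues against shared EtOH arrays as the source. Over the 164 genes BMS961 exceeded BMS641 by 0.04, 0.11 and 0.08 at 24, 48 and 72 h (mean 0.0787, SD 0.0343), which handling or culture time common to all treated arrays would not give. That BMS961 at 0.1 µM may raise genes that ATRA raises early is therefore a hypothesis, found and tested on the same data. The part that BMS641 shares (0.152 in the shorter lists) stays open, since the EtOH arrays carry no time.

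Other divisions of the arrays of each late comparison were counted. For ATRA and BMS753 against EtOH, 1 of 35 splits, the real one, gave as many genes (7362 and 2683, highest other 0 for both). That share is the smallest that 35 splits can give and lies under the share of 0.05 set beforehand. Every other split puts treated and EtOH arrays together, which widens the spread and keeps its count low. The real division thus stands out among these arrays, but the splits cannot exclude chance differences between cultures. For BMS961 against EtOH it was also 1 of 35 (1 gene, highest other 0). For BMS641 against EtOH all 35 splits gave 0 genes, the real one included, and a real count of 0 fixes that outcome, so these splits say nothing. In the fit of the EtOH, BMS641 and BMS961 arrays, 1 of 35 splits, the real one, gave as many genes for BMS641 (191, highest other 23) and for BMS961 (634, highest other 35). The same limit holds there, and that fit was chosen after seeing the data. The pairs of agents allow 10 splits, too few for a share under 0.05. Real and highest other counts were 6348 and 869 for ATRA with BMS641, 6377 and 1 for ATRA with BMS961, 1980 and 0 for BMS753 with BMS641, 1575 and 0 for BMS753 with BMS961 (1 split each as large, the real one), and 0 and 0 for BMS641 with BMS961 (10 splits). In the fit of the EtOH, BMS641 and BMS961 arrays the last pair gave 30 and 2 (1 split as large, the real one). For ATRA with BMS753 2 of the 10 splits were as large, the real one with 2067 genes and another with 3569, in which the ATRA 24 h and BMS753 24 and 48 h arrays were set against the ATRA 48 and 72 h and BMS753 72 h arrays. On the first principal component the ATRA 24 h and BMS753 24 and 48 h arrays scored 14.2, −6.62 and 28.6. The ATRA 48 and 72 h and BMS753 72 h arrays scored 63.0, 78.0 and 55.1. That split thus followed the first principal component and not the agent, and was not tested further.

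Among 146 genes and lists examined in the EtOH arrays, 1 array stood apart for 11, where chance gives about 1 in 20. The gap of that array to its nearest neighbour, divided by the range of the EtOH arrays, was 0.955 for Ccl17, 0.842 for Eomes, 0.835 for Rasgrp3 and 0.887 for the cell cycle list, all in EtOH replicate 2. It was 0.836 for Cited1, 0.909 for Hoxb9, 0.928 for Klf5, 0.860 for the retinoid list, 0.912 for the fibroblast and smooth muscle list and 0.958 for the cholesterol synthesis list in EtOH replicate 1, and 0.878 for Rarg in EtOH replicate 4. The widest distance from the median of the other arrays was −0.24, for Ccl17.

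Opposite calls with ATRA and BMS753 late were made for Hs3st5 (0.30 and −0.21, difference 0.51, adjusted p = 9.83e-04 by limma), Klf4 (0.26 and −0.34, difference 0.60, adjusted p = 0.00319) and Lta (0.20 and −0.19, difference 0.39, adjusted p = 7.46e-04). The genes were chosen by their opposite calls in the same fit, so the adjusted p of the differences is no separate support. Hs3st5 stood at −0.38 to −0.16 in the late BMS641 and BMS961 arrays, so its fall was not particular to BMS753. With BMS753, the late means of Klf4 and Lta lay below all of those arrays (lowest −0.10 and −0.13). The calls of Klf4 with ATRA and between the agents were lost without the 48 h arrays, and that with ATRA also without the 72 h arrays or without EtOH replicate 1, 3 or 4, or after another quantile normalization. With BMS753 the calls of all 3 were lost without the 48 h arrays, those of Hs3st5 and Lta without the 72 h arrays, that of Klf4 without EtOH replicate 2 and that of Hs3st5 without any single EtOH array or after another quantile normalization, which also ended the call of Lta with ATRA. All 3 differences between the agents were lost in the fit of only the groups compared and under the stricter threshold.

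Of the 12146 probe sets not named here, which the comparisons did not use, 1464 were called late with ATRA (912 higher and 552 lower) and 128 with BMS753, and limma called 0 with BMS641 and 0 with BMS961.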

How the results depend on the processing

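The fit of the EtOH, BMS641 and BMS961 arrays alone was chosen after seeing the data, and the other alternatives before. No result changed direction past its threshold under any alternative run, and all alternatives fixed beforehand were run. Leaving out the dimmest genes, averaging probe sets and robust variance moderation left the count of each of the 14 comparisons within 1.5 times its value. Where a count moved, the cause was not tested, apart from the stricter threshold and the smaller number of arrays that some alternatives bring by construction. Where leaving out a time left an early agent with 1 array, that array is assumed to vary like the other groups. Signal over background was not given, so what it limits is unknown.

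An added 2-fold threshold left 939 genes for ATRA and 412 for BMS753 late, 44 and 7 early, 143 between ATRA and BMS753, 901 and 873 between ATRA and BMS641 or BMS961, and 321 and 290 between BMS753 and BMS641 or BMS961. With the spread of the EtOH arrays alone, counts were 6247 for BMS753, 125 for BMS641 and 456 for BMS961 late, 1402, 908, 30 and 70 for ATRA, BMS753, BMS641 and BMS961 early, 7024 between ATRA and BMS753, 5859 and 5591 between BMS753 and BMS641 or BMS961, and 20 between BMS641 and BMS961. With only the groups compared, they were 6255 for BMS753, 115 for BMS641 and 464 for BMS961 late, and 1391, 901, 28 and 70 early in the same order. Against EtOH that fit also takes its spread from the EtOH arrays alone, so counts near the former were fixed by construction. Between agents this fit gave 0 for ATRA with BMS753, 26 and 30 for ATRA with BMS641 and BMS961, 4 and 4 for BMS753 with BMS641 and BMS961, and 69 for BMS641 with BMS961. Without a time term counts were 0 for BMS961 late, 112 and 26 for ATRA and BMS753 early, and 1011 and 641 for BMS753 with BMS641 and BMS961. Another quantile normalization gave 29 for BMS753 early. The fit of the EtOH, BMS641 and BMS961 arrays gave 191 and 634 late, 58 and 109 early, and 30 between BMS641 and BMS961.

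Leaving out 1 EtOH array or 1 time gave 5784 to 8960 genes for ATRA late, 1051 to 5364 for BMS753 late, 0 for BMS641 late and 1 to 7 for BMS961 late. Early counts were 18 to 146 for ATRA, 2 to 31 for BMS753, 0 to 1 for BMS641 and 0 to 2 for BMS961. Between agents they were 317 to 4735 for ATRA with BMS753, 3664 to 7821 and 3526 to 7877 for ATRA with BMS641 and BMS961, 130 to 4350 and 59 to 4247 for BMS753 with BMS641 and BMS961, and 0 for BMS641 with BMS961. Of the calls of named genes, 72 were lost with only the groups compared, 72 without the 48 h arrays, 41 without the 72 h arrays, 39 under the added 2-fold threshold, 23 without a time term, 21 without the 6 h arrays, 20 to 22 without 1 EtOH array, 9 without the 2 h arrays, 11 after another quantile normalization, 7 with robust moderation and 2 without the 24 h arrays. Named genes also gained calls, 22 with the spread of the EtOH arrays alone, 19 with only the groups compared and 17 in the fit of the EtOH, BMS641 and BMS961 arrays. A further 8 were gained without the 24 h arrays and 1 with the dimmest genes left out. With an estimated correlation all 56 list calls were lost.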

Other observations

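The genes named here were chosen after their values were seen. Frzb, a secreted Wnt-binding protein, rose by 2.37 ± 0.41 with BMS753 late against EtOH, Dkk1, a Wnt antagonist, by 1.86 ± 0.36 and the Wnt receptor gene Fzd10 by 1.42 ± 0.28 (adjusted p = 0.00167, 0.00336 and 0.00437, n = 3 and 4, by limma). ATRA minus BMS753, they differed by −1.80 ± 0.44, −1.46 ± 0.38 and −1.35 ± 0.30 (adjusted p = 0.0207, 0.0269 and 0.0144). At 48 and 72 h of BMS753, Frzb stood 3.58 and 3.02 above EtOH, Dkk1 2.56 and 2.97 and Fzd10 2.04 and 2.23, where no ATRA or EtOH array exceeded 0.79, 0.75 and 0.42. Wnt1 stood at 4.18 and 4.63, where no ATRA or EtOH array exceeded 3.50, and its late difference between the agents was not called (−1.04, interval −2.32 to 0.23). No list of Wnt genes was fixed or tested, so this describes these genes only. The differences between the agents were lost for Frzb, Dkk1 and Fzd10 without the 48 h or the 72 h arrays and in a fit of only these arrays, that of Dkk1 also without a time term, and the calls of Dkk1 and Fzd10 against EtOH without the 48 h arrays.

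Sema3d, a secreted guidance protein, stood at 3.19 and 3.84 at 48 and 72 h of BMS753, with the highest ATRA or EtOH array at 1.71. In all, 33 genes lay above and 6 below the range of the ATRA and EtOH arrays by over 0.5 at both times. Hsd17b11, at −2.87 and −3.14, was among those below.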
